A study of Homo sapiens with 2 samples.

How the data were processed

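Quantitative PCR on a human apoptosis gene panel was carried out on LNCaP cells, an established line of human prostate adenocarcinoma cells. There were 2 samples, 1 untreated control and 1 treated with C-PC at 500 µg/mL for 24 h, per the labels. C-PC is C-phycocyanin in the column names of the deposited tables, the blue pigment protein of cyanobacteria. Per the labels' protocols, 1000 ng of total RNA per sample was reverse transcribed, amplified for 40 cycles with SYBR Green, and each sample was run in 3 runs.

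Each of 3 deposited tables held 89 wells named by plate position. The first held the threshold cycle (Ct) of each well in each sample, not normalized, per the file headers. Ct is the cycle at which fluorescence crosses a threshold, so a value higher by 1 means a 2-fold lower template level at full amplification efficiency. The second held the authors' fold change, C-PC over control, calculated as 2 to the power of minus ΔΔCt and normalized to housekeeping genes, per the file headers. The third held a ratio for each well and sample, deposited by the authors without a stated scale. That ratio was checked against the Ct values and equalled 2 to the power of minus the difference between the well and the mean Ct of wells H01 to H05, within 0.01 on the log2 scale in both samples, for 82 of the other 84 wells. The remaining 2 wells had a control Ct just above 35 that the authors' ratio treated as 35. Wells H01 to H05 are therefore called reference wells here, and wells A01 to G12 target wells. For the reference wells themselves the authors' ratios differed from the recalculated ones by up to 0.14 on the log2 scale, and how those were made is not given in the sources used here.

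The files do not pair wells with genes, and no layout of the plate was used. Gene names are therefore not given, and the gene groups chosen before the data were examined, among them caspases, BCL2 family members, death receptors and markers of lymphocytes and myeloid cells, could not be evaluated. The rule for naming, fixed at the same stage, took all detected genes past 2-fold up to 15 each way, the reference genes and the extremes of each gene group. Because positions without gene names carry little meaning, only the 2 highest and the 2 lowest of the target wells detected in both samples are identified, with the 5 reference wells.

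The files give 1 Ct per well and sample. Multiplied by 3, all 89 C-PC values and 87 of 89 control values fell on the grid of single-precision numbers, with a tolerance of 0.02 of a step, where chance gives 4%. Without this multiplication, 34 and 30 values did. This is what means of 3 instrument readings would give. The spread between runs could not be calculated from means. Whether the runs came from separate cultures is not given in the sources used here. They were treated as repeat measurements of 1 sample per group. No test between conditions was therefore made, and no p-value is given. PCR cycles carry no read depth. The number of samples limits the precision.

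For the results here, each target well's Ct difference (C-PC minus control) was corrected by the mean difference of the 5 reference wells, and the sign was turned to give a log2 fold. The SD of the 5 reference wells' own differences is given beside the folds as the spread between single reference wells. The standard error of their mean was 0.17 cycles. The SD includes neither variation between cultures nor the measurement error of the target well. A well counted as detected at a Ct under 35, and a change of at least 2-fold either way was counted. Where a well was detected in 1 sample only, a Ct of 35 was used for the other and the fold is a lower bound. What a deposited Ct of exactly 35 stands for, and why other wells keep values above 35, is not given in the sources used here, so that bounds resting on a 35 hold only if the template was at or below that level. The alternatives were each reference well alone, the 3 reference wells nearest the median shift, the median of all detected target wells (plate median), no reference, the authors' fold changes, Ct limits of 32 and 37 or none, and thresholds of 1.5-fold and 3-fold. A count of wells past 2-fold under 7 references at once was added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The calculation was tested on simulated data, in 200 plates of 65 target wells with an assumed noise of 0.2 cycles. Of wells given a log2 fold of 3, 100% passed 2-fold, of those given 1.5, 94.7% did, of those given -1.5, 92.0% did, of those given -3, 100% did, and of unchanged wells 0.167% did. In the simulation all reference and target wells shared the same shift, and wells with a late control Ct were left out. The rates therefore do not cover the 0.51-cycle offset between reference and target wells, larger differences between reference wells, or late wells.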

Results

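The transcripts of an apoptosis gene panel were measured in LNCaP prostate cancer cells by quantitative PCR, in 1 control sample and 1 sample treated with C-phycocyanin (C-PC) at 500 µg/mL for 24 h. The comparison asked which genes of the panel differed in level between treated and untreated cells. The plate held 84 target wells, each for 1 assay of the panel, and 5 reference wells. With 1 sample per group there was no replicate check on any difference below, and the values describe these 2 samples.

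Ct values ran from 16.0 to 37.4 in the control and from 16.2 to 38.3 in the C-PC sample. Of the 84 target wells, 72 had a Ct under 35 in both samples, 5 in the control only, 2 in the C-PC sample only, and 5 in neither. The median Ct of the 72 wells was 25.4 in the control and 25.5 in the C-PC sample. A Ct of exactly 35 stood in 1 target well of the control and in 6 of the C-PC sample, while 6 and 4 wells had values above 35. Whether a value of exactly 35 marks a well without amplification is not given in the sources used here, and the bounds below take it as a level at or below that of Ct 35.

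All 5 reference wells, the housekeeping wells of the plate, crossed the threshold later in the C-PC sample. The mean shift was 0.76 ± 0.39 cycles (SD over 5 wells of these 2 samples), which amounts to a 1.69-fold lower level. Well H05 shifted by 0.21 cycles and well H04 by 1.21 cycles, with H01 at 0.57, H02 at 0.75 and H03 at 1.03. The reference wells thus differed among themselves by 1.00 cycle. The 72 detected target wells had a smaller median shift of 0.24 cycles, with quartiles at -0.12 and 0.53. Of these, 47 crossed later and 25 earlier in the C-PC sample. The scaling to the reference wells therefore placed the median target well 0.51 higher in C-PC on the log2 scale (1.43-fold), and scaling to the plate median removed this offset.

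**Figure D1:**
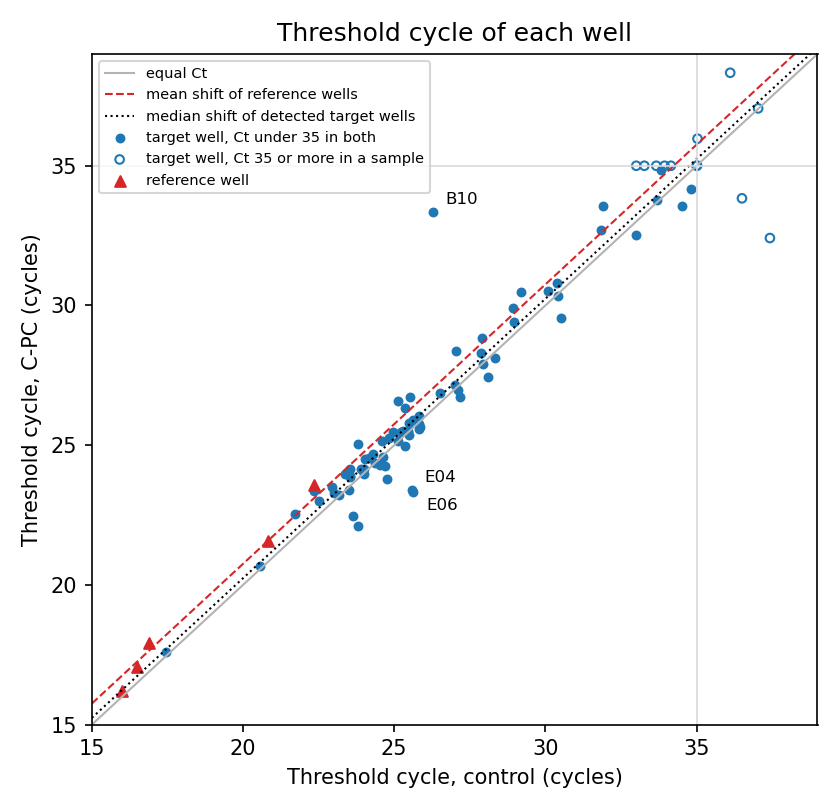
Threshold cycle of each well in the C-PC sample (vertical axis, cycles) against the control (horizontal axis, cycles), 1 point per well and 1 sample per group. Red triangles are the 5 reference wells, filled blue circles the 72 target wells under Ct 35 in both samples, and open circles the other target wells. The dashed line marks the mean shift of the reference wells (0.76 cycles) and the dotted line the median shift of the detected target wells (0.24 cycles). Well B10 lies far above the lines and wells E04 and E06 below them.

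Relative to the 5 reference wells, 15 of the 72 detected target wells were at least 2-fold higher in the C-PC sample, 1 was at least 2-fold lower, and 56 lay between. Relative to the plate median, 7 were at least 2-fold higher, 5 were at least 2-fold lower, and 60 lay between. The share of wells past 2-fold that were higher was thus 93.8% of 16 wells with the reference wells and 58.3% of 12 wells with the plate median. All 7 wells higher by the plate median were among the 15 and were at least 2-fold higher under all 7 of the following references: the mean of the 5 reference wells, each of the 5 alone, and the plate median. Each reference moves all wells by the same amount. Passing all 7 therefore amounts to passing with H05, which shifted least, and is not 7 separate checks. The 7 higher wells include a well near the detection limit, with a Ct of 34.5 in the control and 33.6 in the C-PC sample. Another of them had a control Ct of 30.5. With a Ct limit of 32 and the mean of the 5 reference wells, 12 of 64 wells were at least 2-fold higher. Without any reference, 4 wells were at least 2-fold higher and 9 at least 2-fold lower. The authors' deposited table gave 15 higher and 1 lower among the same 72 wells. It differed from the recalculated folds of the 84 target wells by at most 0.035 on the log2 scale.

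Among the 72 wells detected in both samples, the 2 with the largest increases were E06 and E04. The E06 transcript went from a Ct of 25.6 in the control to 23.3 in the C-PC sample, a level 8.30-fold higher, with a log2 fold of 3.05 ± 0.39 (SD of the reference shifts). Relative to single reference wells its log2 fold lay between 2.51 and 3.51. The E04 transcript was 7.81-fold higher, with a log2 fold of 2.96 ± 0.39 and a range of 2.42 to 3.42 over single reference wells. Relative to the plate median the 2 wells were 5.81-fold and 5.47-fold higher. Both exceeded the spread of the reference wells, but that spread includes no measurement error of these 2 wells, which were picked as the highest of the 72. The other 13 wells past 2-fold were between 2.01-fold and 5.48-fold higher, and 8 of the 15 were below 3-fold. Control Ct values above 30, where little template was present, occurred in 4 of the 15 wells.

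The transcript of well B10 showed the largest difference among the wells detected in both samples. Its Ct was 26.3 in the control and 33.3 in the C-PC sample, a shift of 7.04 cycles. The level was 78.2-fold lower in the C-PC sample, with a log2 fold of -6.29 ± 0.39 and a range of -6.83 to -5.84 over single reference wells. Relative to the plate median it was 112-fold lower. The C-PC Ct of 33.3 was late, and the ± 0.39 includes no measurement error of this well. B10 was the 1 well of the 72 at least 2-fold lower under all 7 of these references. The next lowest of the 72, well F05, had a log2 fold of -0.88 ± 0.39, and its Ct values of 31.9 and 33.6 were late. It was 1.84-fold lower relative to the reference wells and 2.63-fold lower relative to the plate median, so that its place past 2-fold depended on the reference. Besides B10, 4 wells were lower by 2-fold with the plate median, with log2 folds from -1.39 to -1.06.

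**Figure D2:**
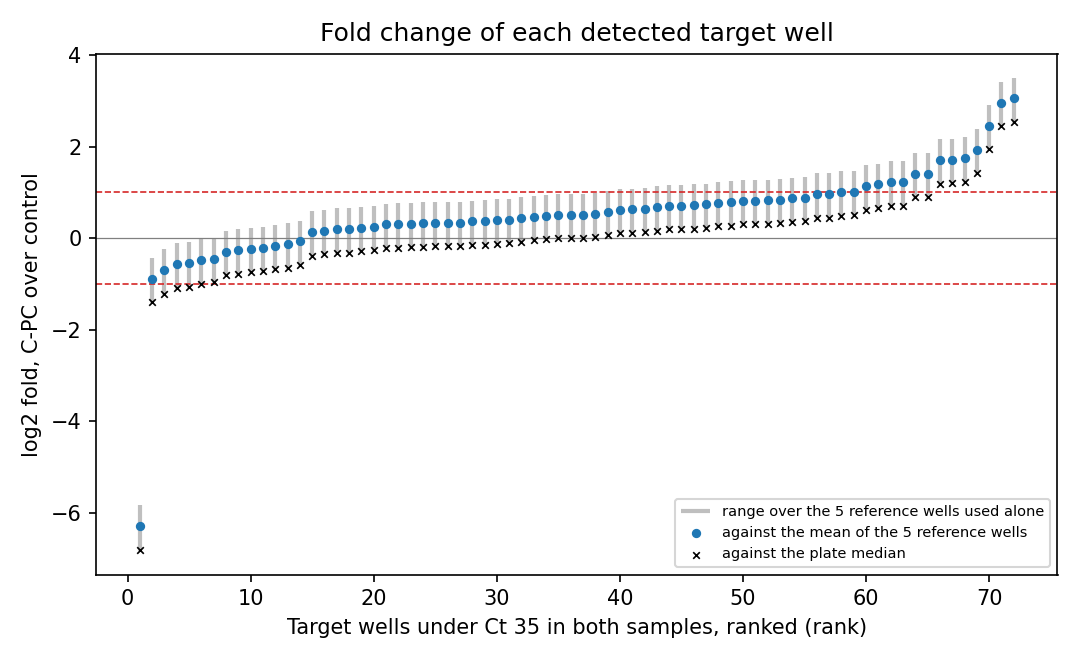
Log2 fold, C-PC over control (vertical axis), of the 72 target wells under Ct 35 in both samples, ranked (horizontal axis), 1 sample per group. Blue points are relative to the mean of the 5 reference wells, grey bars span the 5 reference wells used alone, crosses are relative to the plate median, and the red dashed lines mark 2-fold either way. B10 stands alone at -6.29 and E06 and E04 at the top at 3.05 and 2.96, and every cross lies 0.51 below its point.

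Transcripts near the detection limit could be given only as bounds. In the 2 wells detected in the C-PC sample alone, levels were at least 10.1-fold and at least 3.79-fold higher there relative to the reference wells, and at least 7.10-fold and at least 2.65-fold higher relative to the plate median. The authors' deposited table lists 54.3-fold and 10.7-fold for these wells, from control Ct values of 37.4 and 36.5. In the 5 wells detected in the control alone, control Ct values ran from 33.0 to 34.2 and the C-PC values were all exactly 35. Relative to the reference wells, the level in 1 of them was at least 2.36-fold lower in the C-PC sample, and in the other 4 the bounds lay between 1.07-fold and 1.96-fold. Relative to the plate median, 3 of the 5 were at least 2-fold lower, with bounds of 3.37-fold, 2.80-fold and 2.13-fold. No fold could be given for the 5 wells at 35 or later in both samples. For a well at 35 in both samples the authors' deposited table lists a fold of 1.68, which is the shift of the reference wells alone.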

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

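The scaling to reference wells decided most of the counts. Wells at least 2-fold higher, 15 with the mean of the 5 reference wells, numbered 26 with H03 alone, 34 with H04 alone, 7 with H05 alone, 7 with the plate median and 4 with no reference. Wells at least 2-fold lower, 1 at first, numbered 2 with H01 alone, 6 with H05 alone, 5 with the plate median and 9 with no reference. The median log2 fold of the detected target wells, 0.51 with the mean of the 5, was 0.97 with H04 alone, -0.027 with H05 alone, 0 by construction with the plate median and -0.24 with no reference. The reference shift itself was 1.21 cycles for H04 and 0.21 cycles for H05. A 1.5-fold threshold gave 33 higher and 3 lower, and a 3-fold threshold gave 7 higher. With a Ct limit of 32 no well was lower (0), because B10 at 33.3 in C-PC is then left out, with a limit of 37 there were 2 lower and with no limit 3. Under the other alternatives these counts stayed within 1.5 times and the median and shift within the SD of the reference shifts, and wells E06, E04 and B10 kept their direction and stayed past 2-fold under every reference. In all, 45 of 82 alternative values stayed within these margins, with folds of single wells held to the same SD margin. The 82 values are not separate checks, since each reference moves the wells and their median by the same amount. Leaving out runs and taking their median were not run, since the files used here give 1 value per well and sample, nor were gene group medians, for want of gene names. A pseudocount did not apply to Ct values. No paired analysis was possible because each group has 1 sample. Late Ct values limit what can be seen: of 9 target wells with a control Ct from 33 to under 35, 4 were under 35 in the C-PC sample.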

Other observations

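All tests in this part were chosen after the results were seen. The later crossing of the 5 reference wells in C-PC, which sets the scale of every fold, was weighed first. A shift tied to how early a well crosses stays open. The reference median of 0.75 cycles lay at percentile 98.9 of 10000 random sets of 5 target wells with a control Ct under 24, whose median shift was 0.32 cycles over 18 wells. However, 3 of the 5 reference wells crossed earlier than every target well, the earliest of which had a control Ct of 17.4, so those sets do not reach the cycles in question. A shift that is larger the earlier a well crosses has values against it. The earliest reference well, H05 at a control Ct of 16.0, shifted least (0.21 cycles) and the latest, H04 at 22.3, shifted most (1.21 cycles). The 2 earliest target wells, at 17.4 and 20.6, shifted by 0.18 and 0.11 cycles. The next target wells, at 21.7, 22.3 and 22.5, shifted by 0.82, 1.02 and 0.50 cycles. The target well at 22.3 thus crossed beside H04 and shifted nearly as far. A shift that is larger at later cycles within this range is not opposed by these values. These are too few wells, with no run spread, to exclude a shift tied to the crossing cycle. Less template in every C-PC reaction also stays open, but only for a part of the shift shared by all wells. It would move all wells alike, so by itself it gives no gap between the reference median and the target median of 0.24 cycles. Whether that gap exceeds the scatter of wells was not settled. Among sets of all 72 detected target wells the reference median lay at percentile 95.7, inside the bounds set for it, and the early wells gave a value outside. A gradient down the plate towards row H cannot be told apart either, because Spearman's rho of row with shift across target wells was -0.16 with a 95% bootstrap interval of -0.40 to 0.10, and wells are not independent replicates. The neighbouring row G, tried first, had a median shift of 0.084 cycles with an interval of -0.25 to 0.82, which includes the reference mean. Row A, farthest from H, had the largest row median at 0.59 cycles and row F the smallest at -0.032, the opposite order, but the interval of rho includes 0. A lower level of the reference transcripts themselves under C-PC may also play a part and was not tested, since every level here is relative.

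The second pattern was the 7.04-cycle shift of well B10. If 1 of 3 averaged C-PC runs had failed and counted as the last of 40 cycles, the mean would have risen by 4.57 cycles with the other 2 runs at the control Ct, and by 5.38 cycles with those 2 shifted as far as the reference well that shifted most. Both fall short of the observed shift by more than the SD of the reference shifts, so a single failed run beside such runs does not account for it. If failed runs counted as the last of 40 cycles, failure of more than 1 run would have overshot the observed shift of 7.04 cycles. This holds with any remaining run at the control Ct or later, and argues against that cause at that value. The value given to a failed run is not given in the sources used here. Failure of more than 1 run alone therefore stays open only with a value lower than 40. A true fall of the transcript, and a failed run together with a smaller true fall, also stay open without run-level values. The size of the fall is therefore not settled. The argument takes the deposited Ct as a plain mean of 3 runs, whether of 1 culture or several.

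The third pattern was the earlier crossing of wells E06 and E04 in C-PC. If 2 control runs had matched the C-PC value, the remaining control run would have needed a Ct of 30.2 in E06 and 30.0 in E04, both within 40 cycles. This reckoning leaves out the mean reference shift of 0.76 cycles. With the other control runs earlier by that much, the late run would need a later Ct, which was not calculated. Only a far larger difference could have taken the needed Ct past 40, so the check could hardly exclude this cause. A single late control run in each well stays open, and cannot be told apart from a higher transcript level because only means are given.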
